A study of Mus musculus with 2 samples.

How the data were processed

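Processed DNase-seq files of 2 libraries from embryonic forebrain were analysed, 1 group with the biological replicate numbers 1 and 2 taken from the labels. The labels give different biosamples and the same donor record for both, so the spread between them may be partly technical. Per the labels and the deposited description files, all coordinates are mm10, every file was made per library without pooling, and each derives from alignments of that library. Programs, versions and thresholds are not given in the sources used here.

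Each library has 3 deposited peak lists. The main one, chosen by a rule fixed before the data were examined (the list stated to be nearest a 5% false discovery rate or, with none stated, the one with the middle number of peaks), has peaks of variable width and a deposited value read as normalised to depth (RPM); no source states its normalisation. All of its values are whole multiples of 1 step per library within a tolerance of 0.05 of a step. The step is 0.00467 in replicate 1 and 0.00449 in replicate 2; taking it as 1 read gives the implied depths, which no source states. A shorter deposited list uses the same values. An earlier deposited list has peaks of at most 150 bp with a whole-number count per peak. Deposited hotspots carry the −log10 of their false discovery rate, and a score derived from it that was not used. The deposited false discovery rates per position, a q-value, are listed only up to 0.05. Every peak of the main list held such a position, and the highest per-peak minimum was 0.05 in both libraries; in the shorter list it was 0.000996 and 0.000999, so the main list corresponds to a limit of 5% and the shorter one to a stricter limit near 0.001. Deposited footprints carry a constant p-value column of 0.01, a threshold and not a measurement. The main list, the shorter list, the footprints and the rates used come from a later alignment than the hotspots and the 150-bp list; the rates of the earlier alignment were not used. Peak values are the authors' and were used to rank peaks and to compare shared regions after centring. Peaks within a list can overlap each other (8568 and 5282 did), and no list of problem regions was applied.

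Peaks on chromosomes 1 to 19 and X entered, and Y was used for the sex chromosome share alone. The GRCm38 sequence and the GENCODE M21 annotation were used, with 21728 protein-coding genes. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with bedtools 2.31.1 for overlaps over a share of both peaks and as a check. A promoter peak has its centre within 1000 bp of a TSS of a protein-coding transcript; a distal peak lies farther from all of them. Overlap between libraries needed 1 bp, and its chance level came from 100 circular shifts along each chromosome. Shared regions were merged peaks of both libraries with the highest value of each. Intervals of shares are Wilson 95% intervals.

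The 20 gene lists (370 genes) and the 28 consensus sequences were fixed at the same time. Promoter peaks by list were tested with Fisher's exact test (two-sided) against all other protein-coding genes. Distal peaks were counted within 50 kb of the gene's TSS, averaged over the libraries, and the list median was placed among 10000 random lists matched on neighbouring TSSs. Motif matches on either strand were counted in the central 150 bp of distal peaks and in windows 500 bp to each side that touch no peak. For footprints, extended by 5 bp on each side, equal windows of the same peak outside any footprint were used. A library with 0 matches in the control has no ratio, and the motif is then not called. Adjustment was Benjamini-Hochberg over lists or motifs, with a threshold of 0.05. Replicate ratios by list were set among 10000 random sets of regions matched on mean signal, with no p-value.

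The genes named are a fixed panel of forebrain and control genes, the 2 members of each list with most distal peaks and up to 2 without a promoter peak in either library, the 10 genes with most distal peaks, the 5 strongest distal peaks with the nearest TSS, and the 5 peaks with the largest replicate ratio in each direction among the stronger shared regions. Some genes that this rule takes are not reported here. Alternatives were the other peak lists, windows, overlap limits, backgrounds, top-ranked peaks and each library alone. Added after seeing the data were the removal of peaks under 0.15 RPM, the removal of CpG-rich distal peaks and the matching of regions on GC share.

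The list tests and motif counts were tested on simulated data. Of promoter lists planted at 95%, 63.7% were recovered over 200 rounds, and 81% of those planted at 30%, with calls in 1.04% of unplanted lists. A list at 95% can therefore be missed at these list sizes. The rate for unplanted lists does not cover real lists whose promoters differ from other genes in CpG content. For distal counts of 21728 genes, 93.3% of lists planted at 3 times the count and 100% of those emptied were recovered over 20 rounds, with calls in 0.714% of unplanted lists. The counts were shuffled among genes for this, so the rates do not cover lists whose neighbouring members share peaks. A motif planted in 969 of 20000 random windows was found in 972, as by a direct search. Overlaps of the libraries differed from those of bedtools by 0 peaks.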

Results

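DNase-seq was performed on the forebrain of mouse embryos at 10.5 days of gestation (strain B6NCrl, males and females pooled). In this assay DNase I cuts DNA where chromatin is accessible, and stretches with many cuts are called as peaks. At this stage the forebrain is made mostly of dividing neuroepithelial progenitors, with the first neurons being born. The series holds 1 group with 2 libraries, which the labels number as biological replicates 1 and 2 from different biosamples. No second tissue, age or treatment is present. The comparisons are therefore between the libraries, between gene groups and between DNA motifs within this tissue. The peak values are the authors' and are read here as normalised to read depth (RPM), because all of them are whole multiples of 1 step per library. If that step is 1 read, they imply a depth of 214000000 reads in replicate 1 and 223000000 in replicate 2. All tests describe these 2 libraries, with genes, peaks or footprints as units, and intervals on shares cover counting error only.

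Accessible chromatin was called at 125666 peaks in replicate 1 and 115276 in replicate 2 on chromosomes 1 to 19 and X. Median peak width was 220 bp and 200 bp, and the peaks covered 33.1 Mb and 26.6 Mb, or 1.26% and 1.01% of the sequence. Hotspots, the broader accessible regions, numbered 106977 and 99105. Footprints, short stretches inside accessible DNA that are protected from cutting, numbered 324858 and 278155, with a median length of 9 bp in both libraries.

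The strongly accessible sites were shared by both libraries and most of the weakest ones were not. Of the peaks of replicate 1, 62.7% overlapped a peak of replicate 2 by at least 1 bp (Wilson 95% interval 62.4 to 62.9%). The reverse share was 70.1% (69.8 to 70.4%). Peaks shifted along the chromosomes gave 2.08% and 2.25%. Among the strongest 10% of peaks the share was 99.4% in replicate 1 and 99.2% in replicate 2. Among the weakest 10% it was 9.36% and 1.21%. The shifted shares are for all peaks of a library, and none was computed for the weakest 10%. Merging both lists gave 148138 regions, of which 69276 (46.8%) held peaks of both libraries, 45158 of replicate 1 alone and 33704 of replicate 2 alone. Across the shared regions the values had a Pearson r of 0.952 on the log2 scale and a Spearman rho of 0.940; regions are not independent replicates. Values in replicate 2 were 1.40-fold higher at the median region. Replicate 2 held 10216 peaks valued under 0.15 RPM against 3022 in replicate 1, and 0.891% of them overlapped a peak of replicate 1.

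**Figure D1:**
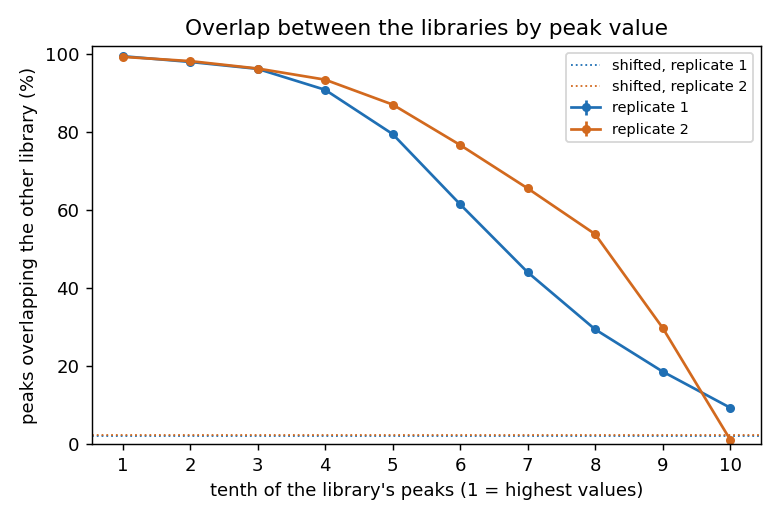
Share of each library's peaks that overlap a peak of the other library (y axis, percent, with Wilson 95% intervals) for 10 equal parts of the library's peaks ordered by value (x axis, 1 the highest). The share falls from 99.4% and 99.2% in the strongest part to 9.36% and 1.21% in the weakest. Dotted lines give the shares for all peaks of the library after shifting, 2.08% and 2.25%.

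Promoters were the class most enriched in accessible sites, while most sites lay away from them. Peaks within 1000 bp of a transcription start site (TSS) of a protein-coding gene made up 24.8% of replicate 1 (24.53 to 25.01%) and 26.4% of replicate 2 (26.2 to 26.7%). Shifted peaks gave 2.53% and 2.54%, so promoters held 9.79 and 10.4 times as many peaks. Other exons held 3.58% and 4.16%, introns 31.1% and 29.2%, and intergenic sequence 40.6% and 40.2%. Introns and intergenic sequence held fewer peaks than after shifting, at ratios of 0.866 and 0.812 for introns and 0.686 and 0.681 for intergenic sequence. Median values were 0.893 and 1.21 at promoters against 0.341 and 0.449 in intergenic sequence. Of 21728 protein-coding genes, 14472 (66.6%) had a promoter peak in both libraries and 6702 had one in neither. The promoter share depended on the list and the window: the mean was 41.1% among the 57638 top-ranked peaks of each library and 18.3% within 500 bp of a TSS, against 25.6% ± 1.17 (SD, n = 2).

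Whether the promoters of a tissue's regulators are accessible in forebrain was asked with 20 gene lists fixed before the data were examined. All 22 forebrain patterning genes had a promoter peak in both libraries, as did all 17 genes of the ventral telencephalon, all 21 of the diencephalon, hypothalamus and eye field, and all 20 neural progenitor genes. Examples are Lhx2, a cortical selector gene (2.30 and 4.55 RPM in replicates 1 and 2), Pax6, a regulator of dorsal progenitors and the eye (2.18 and 4.29), and Six3, which sets up the anterior forebrain (1.51 and 2.22). Otx2 had 1.23 and 1.81, Emx2 2.09 and 3.04, Fezf2 1.44 and 1.86, and Rax 0.949 and 0.947. Of ventral regulators, Nkx2-1 had 1.02 and 1.09, Gsx2 0.790 and 1.16, Dlx1 1.89 and 3.08 and Dlx2 2.66 and 4.37. Among progenitor genes Sox2 had 2.26 and 3.41, Hes5 2.06 and 3.68, and Notch1 2.44 and 3.19. Of 24 early neuron genes 22 had a peak, with Neurog2 at 1.85 and 3.34, Neurod1 at 1.49 and 2.34, Tbr1 at 1.11 and 1.18 and Tubb3 at 1.58 and 2.65; Nhlh1 had none in either library.

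Promoters of regulators that act elsewhere were open too. All 22 mesenchyme and neural crest genes had a peak in both libraries (Twist1, 1.24 and 1.75), as did 18 of 20 midbrain and hindbrain genes (En1, 0.977 and 1.19) and 16 of 17 genes of mature neurons. All 20 cell cycle genes and all 24 housekeeping genes had one, the latter with high values such as Actb at 4.42 and 7.41 and Gapdh at 3.02 and 5.35. These 10 lists were higher than all other genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjusted p from 0.00108 to 0.0381. The call for midbrain and hindbrain ended with the shorter list (80%) and within 500 bp of a TSS (85%), and that for mature neurons with the shorter list (88.2%) and with top-ranked peaks (76.5%).

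Posterior Hox genes, which pattern the trunk and limbs, had a promoter peak in 7 of 18 cases, and blood genes in 7 of 20. Macrophage and microglia genes had one in 3 of 15 cases, skeletal muscle genes in 4 of 15, liver and gut genes in 5 of 17, and pluripotency and germ line genes in 5 of 15. Each of these 6 lists was lower than all other genes (Fisher's exact test, adjusted p from 0.00116 to 0.0284). With promoters widened to 2500 bp around the TSS, skeletal muscle rose to 53.3%, liver and gut to 47.1% and posterior Hox to 44.4%, and the calls for these lists ended. The call for posterior Hox ended with top-ranked peaks (38.9%) and with either library alone, at 66.7% in replicate 2 and 44.4% in replicate 1, and 72.2% of its genes had a peak in at least 1 library; the call for blood ended in replicate 2 alone, at 55%. Without a peak in either library were Hoxa9 and Hoxb9, the erythroid regulator Gata1 and the haem synthesis enzyme gene Alas2, the macrophage genes Adgre1 and Aif1, the muscle genes Acta1 and Ckm, the liver products Alb and Afp, and the germ cell genes Ddx4 and Dppa3. Pou5f1 had a peak in replicate 2 alone (0.727). Myod1, the muscle determination gene, did have one, at 0.453 and 0.826, as did Hoxd13 at 1.40 and 1.52, and Hoxb1, a hindbrain Hox gene, had one in replicate 1 alone (0.477). Endothelial (9 of 17), surface ectoderm (11 of 15), heart (11 of 17) and mature glia genes (8 of 14) did not differ from other genes past the threshold, with Kdr at 1.63 and 2.29 and Nkx2-5 at 0.837 and 0.731, and no peak at Cdh5, Emcn, Krt5, Krt14, Myh6, Nppa, Gfap or Mag. Most of the calls were lost in a comparison with promoters of like CpG content. Against random lists matched on the CpG observed/expected ratio, 3 of the 16 calls held: mesenchyme and neural crest stayed higher (100% against 75.9%, permutation adjusted p = 0.0027), and posterior Hox (38.9% against 94.9%, permutation adjusted p = 0.0020) and pluripotency and germ line (33.3% against 77.4%, permutation adjusted p = 0.0020) stayed lower. Not called were forebrain patterning (100% against 85.7%, permutation adjusted p = 0.0667), early neurons (91.7% against 75.2%, permutation adjusted p = 0.0584), liver and gut (29.4% against 54.2%, permutation adjusted p = 0.0584), housekeeping (100% against 89.6%) and mature neurons (94.1% against 77.0%), among others. For the ventral telencephalon, diencephalon, neural progenitor, midbrain and hindbrain and cell cycle lists the random range reached 100%, which left little room for a higher call. The CpG ratio was taken within 500 bp of the gene's TSS, while a promoter peak could lie at the TSS of any protein-coding transcript. The number of TSSs per gene was not matched.

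Distal peaks were concentrated around regulators of development, within the forebrain programme and beyond it. Each peak record counts, also where records overlap. In replicate 1 the record 109984441 to 109985100 near Dmrta2 lies inside 109984161 to 109985480, and both count. The counts can therefore exceed the number of separate sites, and merged counts were not computed. The forebrain patterning genes had a median of 29.5 distal peaks within 50 kb of the TSS (mean of both libraries; 32 in replicate 1 and 24 in replicate 2), against 3.25 for random lists with as many neighbouring TSSs. The median was 25.5 for the ventral telencephalon, 18.5 for the diencephalon, hypothalamus and eye field, 15.25 for neural progenitors and 6.5 for early neurons. It was 20 for midbrain and hindbrain genes, 30 for posterior Hox, 15.75 for mesenchyme and neural crest and 11 for heart. Mature neuron genes (7), mature glia genes (6.75) and surface ectoderm genes (6.5) lay just above their random range. These 12 lists exceeded the random lists by a two-sided permutation test with Benjamini-Hochberg adjustment, in which p was 0.0002 (adjusted 0.0005), the smallest the permutations can give, for 8 of them. The adjusted p was 0.00533 for early neurons, 0.0192 for mature neurons, 0.0371 for mature glia and 0.0493 for surface ectoderm. Blood, macrophage, endothelial, skeletal muscle, liver and gut, pluripotency, cell cycle and housekeeping genes were not called, with medians from 4.5 to 6 and adjusted p from 0.0986 to 0.413, and no list was called lower. Some of them were called higher in alternatives: macrophage genes with the shorter list, top-ranked peaks and a 100-kb window, liver and gut genes with the shorter list, top-ranked peaks and the mean in place of the median, and endothelial genes with the earlier 150-bp list and in replicate 1 alone. Neighbouring list members, such as Hox genes of one cluster, share the same peaks, so these p-values are too small for such lists and their medians can count a peak more than once. With each peak given to its nearest TSS alone, at any distance, the median fell to 3 for posterior Hox (random median 0, permutation adjusted p = 0.0005) and to 5.5 for heart (random median 2, permutation adjusted p = 0.0464), while it was 41.25 for forebrain patterning, 22.75 for midbrain and hindbrain and 16.5 for mesenchyme and neural crest; these 5 lists were still called above their random lists. Without a distance limit, a gene far from other TSSs can collect more peaks from a longer stretch of sequence. The random lists were matched on neighbouring TSSs and not on that stretch, so these counts do not settle the excess. The calls for surface ectoderm and mature glia ended with nearest-TSS counts, with either library alone and without peaks under 0.15 RPM. That for mature neurons ended in replicate 1 alone, within 100 kb, with the mean in place of the median and without CpG-rich peaks. Surface ectoderm also lost it with the shorter list, top-ranked peaks, a 100-kb window, the mean and without CpG-rich peaks, and mature glia with the shorter list, top-ranked peaks and the mean.

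Over all genes the median was 3.5 distal peaks and the 95th percentile was 14. The gene with most was Nr2f2, a nuclear receptor gene expressed in caudal and ventral forebrain and in venous endothelium (chromosome 7, 70351944 to 70366735; 69 and 64 peaks). Cbx8, which encodes a Polycomb protein, had 63 and 61. Also among the 10 highest were the heart and limb regulator Hand2 (chromosome 8, 57320983 to 57324633; 59 and 60), the neighbours Zic1 (55 and 59) and Zic4 (51 and 57), Sox2 (chromosome 3, 34650405 to 34652461; 61 and 46), and Foxf1 and its neighbour Mthfsd (52 and 54 each). Dmrta2, a cortical patterning gene (chromosome 4, 109978053 to 109983687), had 29 and 82, of which 42 in replicate 2 were valued under 0.15. Within the lists, Dlx5 and Dlx6 had 54 and 41 peaks each, of which 13 in replicate 2 were valued under 0.15, Barhl2 had 43 and 35, Pax3 48 and 39, Onecut2 28 and 23, Ebf3 25 and 25, En1 35 and 36, and Lmx1b 37 and 33. Pax6 had 47 and 33, Six3 36 and 24, and Nkx2-1 34 and 24.

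Regulators of other tissues with many distal peaks were Foxc2 (51 and 53), Tfap2a (44 and 39), Gata4 (56 and 36), Pdx1 (52 and 34) and Cdx2 (45 and 35). The liver and gut list as a whole was not called in the main analysis. Pdx1 and Cdx2 are neighbours on chromosome 5, and Foxc2 is a neighbour of Foxf1 on chromosome 8. Their windows overlap, so their counts can hold the same peaks. Hoxd8 had 29 and 70, and Hoxd9 30 and 63, with a promoter peak in replicate 2 alone for both. Among the highest members of the remaining lists were Lyl1 (27 and 24) and Tal1 (18 and 19) for blood, Fcgr3 (30 and 28) and C1qb (14 and 12) for macrophages, Fli1 (19 and 15) and Flt1 (15 and 12) for endothelium, Des (16 and 7) and Tnnt3 (7 and 13) for muscle, Tfap2c (18 and 14) for surface ectoderm, Slc32a1 (20 and 17) and Slc17a6 (13 and 9) for mature neurons, Gfap (13 and 11) for glia, Utf1 (12 and 15) and Mael (11 and 10) for pluripotency and germ line, Aurkb (21 and 23) and Mcm2 (13 and 12) for the cell cycle, and Actb (14 and 11) for housekeeping. The keratin gene Krt14 had 4 in replicate 1 and 47 in replicate 2, of which 41 were valued under 0.15, and S100b had 4 and 21, of which 12 were.

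**Figure D2:**
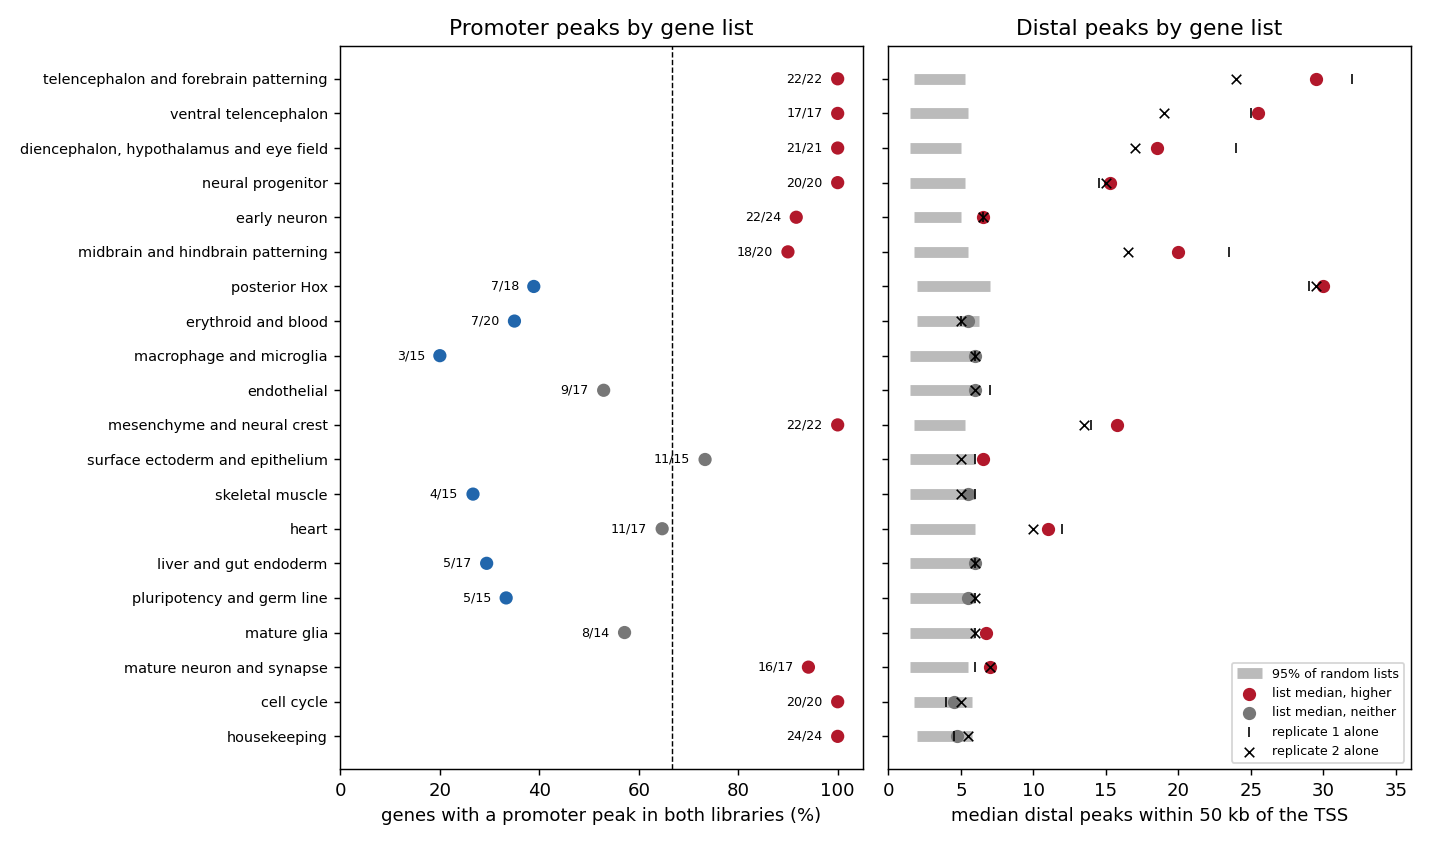
Left, percent of the genes in each of the 20 lists with a promoter peak in both libraries (numbers give genes with a peak and genes in the list; the dashed line marks all genes, 66.6%). Right, median distal peaks within 50 kb of the TSS per list, with the 95% range of 10000 random lists in grey and each library alone as black marks. Red is higher, blue lower and grey neither at an adjusted p under 0.05; forebrain patterning genes stand at 22 of 22 and 29.5, posterior Hox genes at 7 of 18 and 30.

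**Figure D3:**
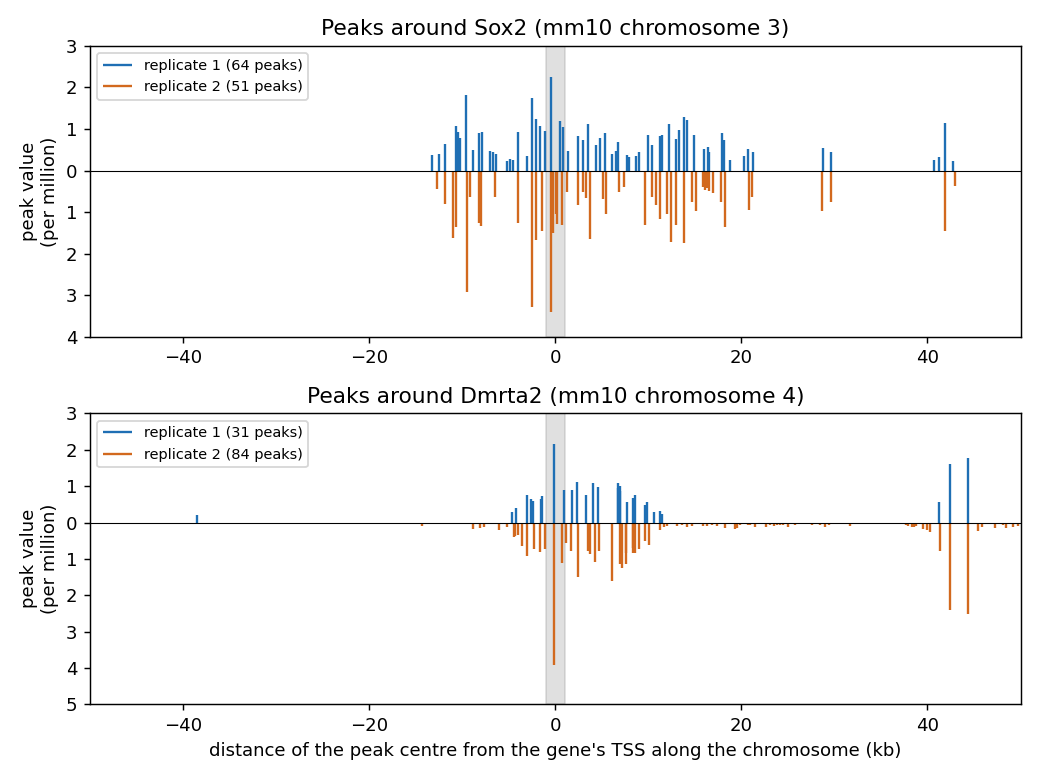
Peaks within 50 kb of the TSS of Sox2 and Dmrta2 in mm10, drawn at their centres (x axis, kb) with their value in RPM (y axis), replicate 1 upwards and replicate 2 downwards; the grey band marks the promoter window. Around Sox2 both libraries show dense peaks (61 and 46 distal ones; the counts drawn in the legends include promoter peaks); around Dmrta2 replicate 2 adds a row of 42 peaks under 0.15 RPM.

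The distal sites were enriched over their flanks for the binding sequence of CTCF, the insulator protein, and for some sequences bound by neural regulators. Those of LHX/DLX, OTX, SOX and NEUROG/NEUROD were not called in the main analysis. Of 28 consensus sequences fixed before the data were examined, 14 were enriched in the central 150 bp of distal peaks over flanking windows in both libraries (ratio of at least 1.5 and adjusted p under 0.05 by Fisher's exact test). The flanks were not matched on base composition, so a different GC share of peak centres and flanks could contribute to the ratios. CTCF stood at 152-fold (95% interval 117 to 197) and 120-fold (94.2 to 153) and occurred in 5.73% and 6.01% of distal peaks. Among sequences bound by factors known in the embryonic brain, the ASCL E-box of proneural proteins was 2.35-fold and 2.40-fold enriched and present in 3.78% and 4.14% of peaks. RFX, bound by ciliary and neural regulators, stood at 3.14 and 3.52, ZIC at 2.93 and 2.82, PBX-MEIS at 2.29 and 2.19, and GLI, bound by the effectors of hedgehog signalling, at 2.38 and 2.27. PAX6 (7.21 and 4.66) and NFI (5.02 and 3.24) were enriched but rare, with 23 and 15 peaks for PAX6 and 32 and 25 for NFI. Neither was called in the central 50 bp, where few matches remained. These were 8 and 3 for PAX6 (ratios 6.59 and 2.48) and 5 and 8 for NFI (1.65 and 13.2). NFI was not called with the shorter peak list either (4.17 and 2.65). REST, a repressor of neuronal genes outside neurons, stood at 2.91 and 3.11. Sequences of broadly expressed factors that were enriched were NRF1 (5.23 and 8.48), YY1 (2.31 and 9.33), SP/KLF (2.77 and 3.29), CREB (2.43 and 2.77) and ETS (mean 1.55 ± 0.065, SD, n = 2). YY1 was not called in the central 50 bp (2.88 and 18.2, on 7 and 11 matches), nor ETS with the shorter peak list (1.48 and 1.66). SOX, the most frequent (7.73% and 7.27% of peaks), and the NEUROG/NEUROD E-box passed the test but stayed under the ratio of 1.5, with means of 1.47 ± 0.0425 and 1.48 ± 0.0195. Both were called in the central 50 bp (1.56 and 2.01), and the NEUROG/NEUROD E-box also with the shorter list (1.59), without peaks under 0.15 RPM (1.51) and against its reversed sequence (6.48). TEAD reached it in replicate 1 alone (1.58 and 1.43). Against their reversed sequences TEAD (mean 3.96), TCF/LEF (3.40) and RBPJ (1.61) were called enriched. The LHX/DLX homeodomain sequence stood at 1.10 and 0.751, although it was called enriched against its reversed sequence (mean 1.79), and OTX at 0.941 and 0.815 (1.04 against its reversed sequence). GATA was lower than in the flanks at 0.705 and 0.671, short of the limit for a depletion in both libraries. It was called depleted with the shorter list (0.607) and in promoter peaks (0.474), and stood at 1.00 against its reversed sequence. The enrichments of ETS and CREB turned to a depletion against their own reversed sequences (mean ratios of 0.246 and 0.439), which lack the CpG that both hold, and that of GLI ended (0.971). YY1 had 25 matches against 0 reversed ones in replicate 1, which has no ratio and so no call, and 36 against 2 in replicate 2. Reversed YY1, and some variants of the reversed NEUROG/NEUROD E-box, TEAD and TCF/LEF sequences, hold more CpGs than the consensus. Their comparisons with the reversed sequence are therefore not matched on CpG content and do not by themselves show an enrichment.

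Inside the peaks, the sequences of CTCF and NRF1 had the highest ratios in footprints over the rest of the peak. Against equal windows of the same peak outside any footprint, the mean ratio over the libraries was 129 ± 16.4 (SD, n = 2) for CTCF and 84.9 ± 1.24 for NRF1. The ratio of NRF1 rests on 4 control matches per library (95% intervals 32.0 to 230 and 31.3 to 225), and its sequence was rare, in 0.128% and 0.146% of footprints, against 1.68% and 1.83% for CTCF and 1.55% and 1.90% for SP/KLF. The mean ratio was 12.2 ± 0.419 for CREB, 9.5 ± 0.707 for NFI (9 and 10 footprints alone), 8.16 ± 1.05 for SP/KLF, 6.17 ± 0.373 for RFX, 5.88 ± 0.860 for REST, 4.67 ± 0.510 for ETS, 2.74 ± 0.271 for GLI and 2.46 ± 0.00688 for the NEUROG/NEUROD E-box. ZIC (1.93 ± 0.147), TCF/LEF (1.87 ± 0.335) and YY1 (1.85 ± 0.315) were also enriched, 13 sequences in all, and GATA was depleted (0.573 ± 0.0692). Against their own reversed sequences in the same footprints the calls for GLI (mean ratio 1.58) and GATA (0.960) ended. NRF1 stood at 343 matches against 0 reversed ones in replicate 1 and 336 against 3 in replicate 2, and YY1 at 184 against 0 and 172 against 1; a library with 0 control matches has no ratio and so no call, and in both libraries the matches far outnumbered the reversed ones. Without the extension of the footprints NRF1 had 333 matches against 0 and 326 against 1, which gives no call for the same reason, NFI 4 against 0 and 6 against 0, and the YY1 call ended (ratios 2.10 and 1.00). The ASCL E-box (1.31 ± 0.0391) and SOX (1.41 ± 0.0173) did not reach the ratio of 1.5, but were called against their reversed sequences (mean ratios 35.8 and 2.46). The reversed ASCL E-box holds a CpG that the consensus lacks, and reversed NRF1 and YY1 hold more CpGs than theirs. These comparisons are therefore not matched on CpG content and do not by themselves show an enrichment. Base preference of DNase I was not modelled, and sequences that it cuts poorly could be called as footprints.

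**Figure D4:**
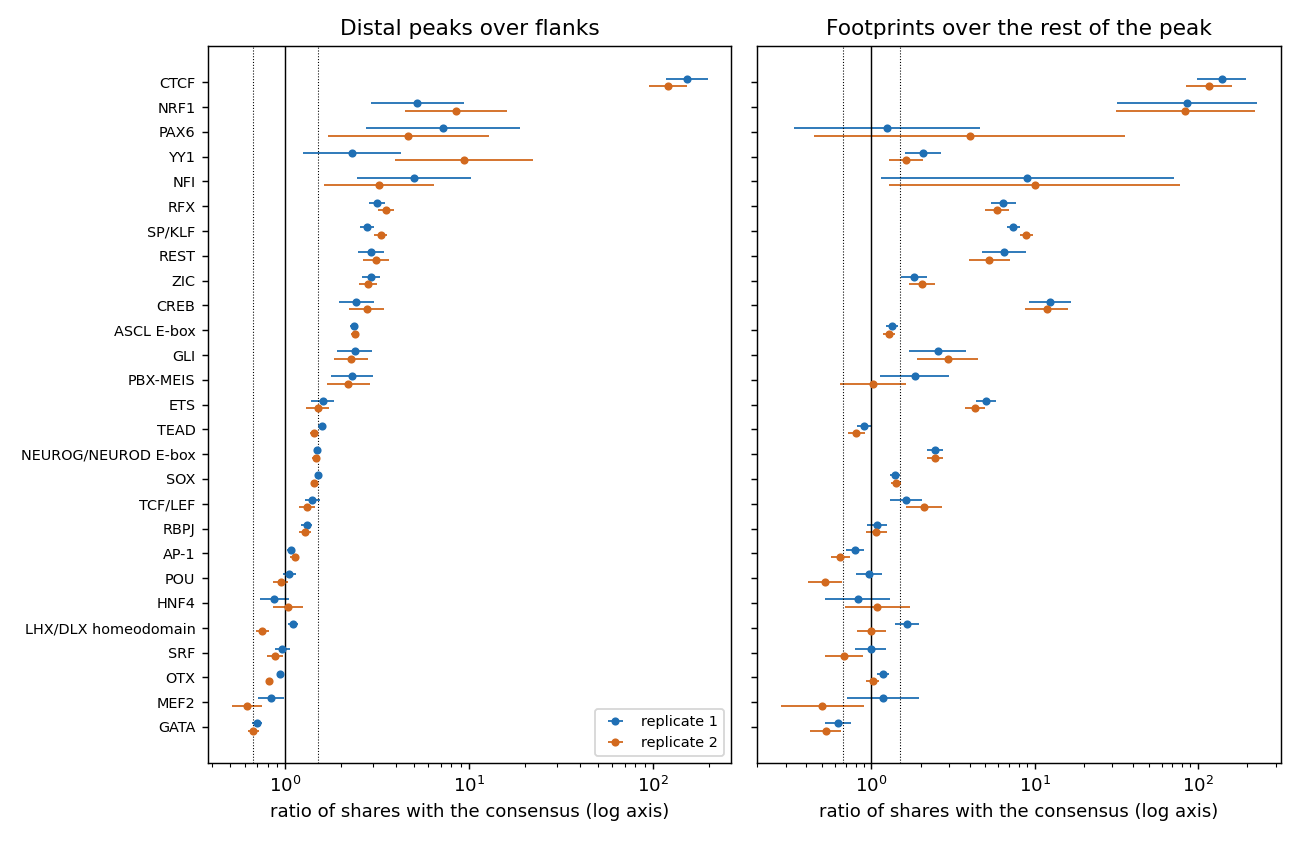
Ratio of the share of windows with each consensus (log axis) in distal peaks over flanks (left) and in footprints over the rest of the same peaks (right), per library with 95% intervals; dotted lines mark 1.5 and its inverse. CTCF lies at 152 and 120 in peaks and at a mean of 129 in footprints, while GATA lies under 1 in both panels; HNF1, with almost no matches, is not drawn.

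Individual footprints recurred between the libraries above the shifted level, in a share that depended on the overlap required. Of footprints in peaks shared by both libraries, 34.2% of replicate 1 (34.0 to 34.5%) and 35.2% of replicate 2 (35.0 to 35.4%) overlapped one of the other library over at least 50% of both. Shifting by 100 bp gave 5.86% and 6.12%. With median peak widths of 220 bp and 200 bp, this shift can carry footprints out of their peaks. The shifted shares may therefore understate the overlap of footprints that merely crowd in the same peaks. With 1 bp of overlap the shares were 49.3% and 50.3% (mean after shifting 18.3%), and with 80% of both 13.3% and 13.7% (0.926%). In replicate 1 84.9% of footprints, and in replicate 2 85.5%, were centred in the library's own peaks.

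In regions shared by both libraries, signal around developmental regulators was relatively higher in replicate 1. Signal around mature glia, pluripotency and housekeeping genes was relatively higher in replicate 2. Peaks of 1 library alone do not enter. Before centring, the median log2 ratio of replicate 1 over replicate 2 was -0.488, and no list's centred ratio reached that size. Peak numbers around posterior Hox genes showed no excess in replicate 1. Their median distal peaks were 29 and 29.5 in replicates 1 and 2, with a promoter peak at 8 and 12 genes. After centring on the median ratio of all shared regions, the median log2 ratio of replicate 1 over replicate 2 was 0.36 for posterior Hox, 0.25 for the diencephalon list, 0.22 for midbrain and hindbrain and for mesenchyme, 0.21 for the ventral telencephalon, 0.20 for forebrain patterning, 0.19 for heart, 0.10 for early neurons and 0.03 for neural progenitors. These 9 lists lay above the 95% range of 10000 random sets of regions matched on signal. Mature glia (-0.13, random median -0.00897) and pluripotency and germ line genes (-0.12, random median 0.02) lay below it, as did housekeeping genes by a narrow margin (-0.18, random median -0.13). Mature glia lay within the range over distal peaks alone (-0.09). Blood (-0.13), macrophage (-0.10), endothelial (-0.000755), surface ectoderm (-0.06), muscle (-0.09), liver and gut (0.07), mature neuron (-0.03) and cell cycle genes (-0.16) lay within it, blood at its very edge. In alternatives blood lay below the range over distal peaks alone (-0.14) and with ranks, muscle with ranks and mature neurons within 100 kb (-0.09), and liver and gut lay above it with regions matched on GC share. With 1 library on each side there is no p-value, and the differences describe these libraries. The random regions were drawn singly, while those of a list cluster around its genes. If neighbouring regions share their ratio, the random ranges are too narrow. Small margins, such as that of neural progenitors over their upper limit of 0.0275, therefore decide little.

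**Figure D5:**
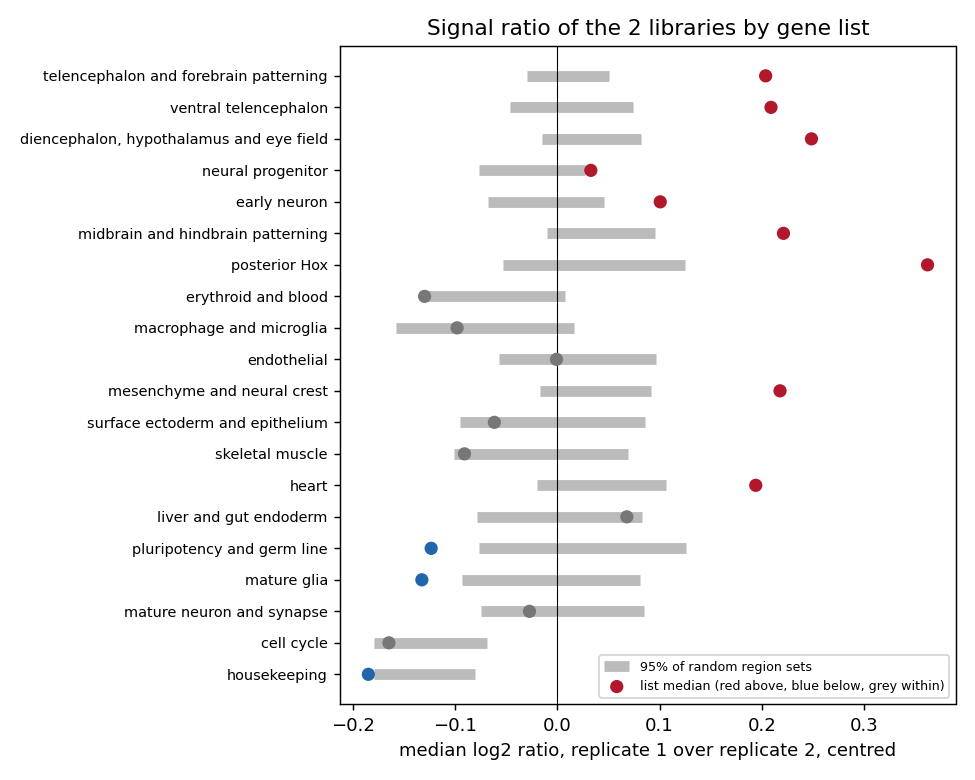
Median log2 ratio of the peak value in replicate 1 over replicate 2, centred on all shared regions, for regions within 50 kb of each list's genes (points), with the 95% range of random sets of regions in grey. Posterior Hox (0.36) lies above its range, and housekeeping (-0.18) just below its own.

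Among shared regions in the upper part of the signal range, the largest relative excess in replicate 1 was in an intron 3893 bp from the TSS of Cldn34d (chromosome X, 76598901 to 76599160), with a centred log2 ratio of 2.06. Intergenic sites nearest to the TSSs of Igf2bp3 (1.94, 21594 bp away), Arrdc3 (1.81, 260253 bp), Hrh4 (1.80, 20301 bp) and Epha7 (1.77, 636160 bp) followed. In replicate 2 the largest was intergenic, 30187 bp from the TSS of Zcchc12 (chromosome X, 36225901 to 36226280), at -1.36. Intergenic sites nearest to Kcnh5 (-1.32, 373401 bp away) and Rd3 (-1.21, 12969 bp) came next. Intronic ones nearest to Tacc1 (-1.20, 40641 bp) and Ms4a10 (-1.19, 5241 bp) followed. A link between these sites and the nearest genes was not tested. The strongest distal site of all was intergenic, 35530 bp from the TSS of Pak3 (chromosome X, 143482981 to 143483140; 56.1 and 40.3 RPM). The next was in an exon of a gene, 16725 bp from the TSS of Limd1 (chromosome 9, 123461901 to 123462060, 15.2 and 30.9). Others were nearest to Cr2 (15.3 and 21.7, 64975 bp away), in an intron nearest to Kpna1 (10.9 and 17.2, 2981 bp) and nearest to Cd209a (8.59 and 16.4, 5487 bp). No list of problem regions was applied to these sites.

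The sex chromosomes held few of the peaks. Chromosome X, with 6.28% of the sequence, held 3.03% of peaks in replicate 1 (2.94 to 3.13%) and 2.81% in replicate 2 (2.71 to 2.90%). Chromosome Y, with 3.37% of the sequence, held 43 peaks (0.0342%) and 72 peaks (0.0624%). Without peaks under 0.15 RPM its mean share fell from 0.0483% to 0.0256%. Both libraries came from embryos of both sexes, per the labels.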

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

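The removal of peaks under 0.15 RPM, the removal of CpG-rich distal peaks and the matching on GC share were chosen after seeing the data. No paired analysis was possible because there is 1 group. With 1 library left out, overlap, correlation, footprint agreement and replicate ratios have no value. A consensus that reads the same reversed (SP/KLF) has no reversed control. The cause of the changes below was not tested, except where stated.

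The mean overlap of 66.4% was 60.1% with the earlier 150-bp list, 87.3% with top-ranked peaks and 44.3% when 50% of both peaks had to overlap. Pearson r and Spearman rho were 0.948 and 0.936 with the 150-bp list, 0.9503 and 0.941 with the shorter list, 0.917 and 0.898 for distal peaks alone, and 0.955 and 0.949 at 50% of both. The mean promoter share of 25.6% was 34.6% with the shorter list, 41.1% with top-ranked peaks and 27.0% without peaks under 0.15 RPM; by construction it moved with the window, to 18.3% at 500 bp and 33.8% at 2500 bp. It was 24.8 to 26.4% with a library left out. Footprint agreement of 34.7% was 49.8% at 1 bp, 13.5% at 80% of both, by construction, and 40.5% in the stronger peaks. The share on X was 2.92%, and 2.70% with the shorter list and without peaks under 0.15 RPM; that on Y was 0.0483%, and 0.0256% without them.

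Of promoter lists, 10 were higher and 6 lower. With random lists matched on CpG ratio 1 was higher and 2 were lower, and midbrain and hindbrain (90% against 90.5%) and blood (35% against 30.4%) turned direction. Within 2500 bp 3 were lower, without posterior Hox (44.4%), skeletal muscle (53.3% against 26.7%) and liver and gut (47.1% against 29.4%). Posterior Hox turned to 72.2%, not called, with a peak in either library. Of 12 distal lists called higher, 9 to 12 kept the call in each alternative; surface ectoderm, mature glia and mature neurons lost it in some. With nearest-TSS assignment the median moved from 30 to 3 for posterior Hox, from 11 to 5.5 for heart and from 29.5 to 41.25 for forebrain patterning. With a library left out, 10 promoter lists were higher, 4 to 5 lower, and 10 distal lists higher.

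Of distal motifs, 14 were enriched and 0 depleted. Against promoter flanks, in promoter peaks, 9 were enriched and 5 depleted, and NFI turned to 0.949. The shorter list gave 1 depleted (GATA, 0.607) and lost NFI (mean ratio 3.41) and ETS (1.57). The central 50 bp lost PAX6 (4.53), NFI (7.43) and YY1 (10.5). A call needs both libraries, and for each motif lost here 1 library fell short. The central 50 bp gained SOX (1.56) and the NEUROG/NEUROD E-box (2.01). Against reversed sequences 2 were depleted. ETS (0.246), CREB (0.439) and GLI (0.971) turned down, and the LHX/DLX homeodomain (1.79), POU (18.2) and MEF2 (1.80) turned up. The reversed POU sequence, and some variants of the reversed TEAD sequence, hold a CpG that the consensus lacks. Their ratios, here and in footprints, are therefore not matched on CpG content. With a library left out, 0 to 1 were depleted. In footprints 1 was depleted, against 0 with reversed sequences, where POU (37.1) and TEAD (5.24) turned up, 4 without the extension and 1 to 4 with a library left out. Of replicate ratios by list, 3 lay below the range, and 5 when ranks were used. Most of the single results that had a value in the alternative kept their call (motifs without a ratio are left out): 174 list results for promoters, 172 for distal peaks, 188 for distal motifs, 84 for footprint motifs and 74 for replicate ratios were the same, against 26, 28, 33, 21 and 6 that changed.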

Other observations

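The test of tissue mixture was chosen after its result was seen, and so were the limit of 0.15 RPM, the 20-kb bins, the minimum of 5 peaks a bin and the limits of a CpG-rich peak. The other tests were written down before their results, on patterns noticed in the same data.

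CpG-rich sites (GC share of at least 50% and CpG observed/expected of at least 0.6) made up 6.44% of distal peaks in replicate 1 and 8.37% in replicate 2, against 56.0% and 60.4% of promoter peaks. The share was 14.6% and 17.7% around forebrain patterning genes, 16.3% and 21.8% around neural progenitor genes and 18.1% and 22.5% around early neuron genes. It was not particular to neural genes, with 15.2% and 20.3% around blood genes and 11.8% and 14.1% around housekeeping genes. Around mature glia genes it was 5.32% and 4.17%, and around posterior Hox genes 9.26% and 23.1%. The shares of these lists were not tested against random genes.

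Several regulators of other tissues had many distal peaks in forebrain, with list medians of 30 for posterior Hox, 20 for midbrain and hindbrain and 11 for heart. These counts can hold a peak for several neighbouring genes, and overlapping peak records of one stretch count separately. With each peak given to its nearest TSS alone, at any distance, the medians were 3, 22.75 and 5.5, still called above the random lists (heart at a permutation adjusted p of 0.0464). Those random lists were not matched on the stretch of sequence from which a gene collects peaks. A candidate explanation is that CpG-rich elements of such genes are open in any tissue. In replicates 1 and 2, CpG-rich peaks were 9.26% and 23.1% of the distal peaks around posterior Hox genes. They were 15.6% and 22.3% around midbrain and hindbrain genes, and 10.9% and 13.2% around heart genes. Without them, 3 of the 3 lists were still called above the random lists, with medians of 22.25, 15 and 11. So small a removed share left little room for another outcome. The shares themselves argue against CpG-rich elements, by these limits, as the whole cause. Other cell types in the dissection stay open, and no biological explanation was tested.

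Replicate 2 held 7409 of its 10216 peaks under 0.15 RPM in 729 bins of 20 kb with at least 5 such peaks each, 0.554% of the sequence, against 92 peaks in 6 bins in replicate 1. Repeated sequence is argued against, since the median soft-masked share of these bins was 28.2% against 30.5% for all bins, a difference of -2.32 percentage points. A lower local calling threshold may contribute: the median −log10 of the false discovery rate was 4.59 for the clustered peaks and 1.84 for peaks of 0.15 to 0.30 RPM outside the bins, a difference of 2.75 (95% bootstrap interval 2.65 to 2.82) although their values were lower. Regulatory elements open in 1 dissection stay open too, since the clustered distal peaks held an enriched motif 1.51 times as often as their flanks (1.26 to 1.81), against 3.09 times (2.77 to 3.46) for the peaks outside. The enriched motifs had been called on distal peaks that include the clustered ones, and with 1 group no biological difference between groups could be tested.

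In shared regions and after centring, replicate 1 was relatively higher around 9 lists. The random ranges used here came from regions drawn singly, and may be too narrow for regions clustered around the same genes. Across shared regions the log2 ratio fell with GC share (Spearman rho -0.33), but 9 of the 9 lists stayed above their range with random regions matched on GC share as well as signal, which argues against base composition as the whole cause. Over distal regions alone 9 of the 9 lists lay above the range too, which argues against a contrast of promoters with distal peaks; the bounds of both tests had been written for 8 lists. A different mixture of tissues in the dissections stays open. Of the 6 lists of other cell types not called for distal peaks in the main analysis, 0 lay above the range, 1 (pluripotency and germ line) below and 5 within it, which decides nothing. The tally is not firm: blood lay at the edge and fell below the range over distal peaks alone and with ranks, muscle fell below with ranks, and liver and gut lay above with matching on GC share. The heart, posterior Hox and mesenchyme lists lay above the range, but their many distal peaks kept them out of the tally. Whether those peaks come from forebrain cells or from other cells was not measured, so these lists decide nothing either way. The degree of digestion, peak calling and dilution by blood were not tested and stay open, and with 1 group no biological difference between groups could be tested.

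Copies of mitochondrial DNA were looked for in the 5 strongest distal peaks, as a source of excess reads; 0 of their 820 words of 25 bases occurred in the mitochondrial genome, and their soft-masked share ran from 0% to 31.9%.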
